A study of Homo sapiens with 2 samples.

How the data were processed

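RNA from 2 established human cell lines, K562 and MOLT4, was measured by RNA sequencing. Per the labels' protocols, each line was grown in DMEM with 10% fetal bovine serum and 1% penicillin and streptomycin at 37 °C and 5% CO2, RNA was taken from 1 flask with a Qiagen RNeasy kit, and libraries followed an Illumina protocol. The series' design text states 3 biological replicates. The groups are the cell lines, taken from the sample titles.

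Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.1.1, Cufflinks 2.2.2 and Cuffdiff were used, and the builds named are GRCh38.p13 and hg38. The deposited values are FPKM, fragments scaled to transcript length and to the number of mapped fragments, with 1 value per gene and cell line. The series lists 1 sample per line and its design text alone states replicates, so whether the authors' values and q-values combine 3 libraries per line is not given in the sources used here. If they rest on 1 library per line, the q-values compare those libraries and not the lines. The authors' deposited table also holds a p-value and a q-value per gene from Cuffdiff. Values per replicate and read counts were not used here, so no SD, standard error or test across replicates could be computed, the depth is unknown, and no interval that needs depth is given. How the normalization between lines was set is not given in the sources used here. Strand use in the counting is not given either, so overlapping and antisense genes cannot be separated, and values of near-identical copies (HBA1 and HBA2, GAGE, MAGE-A, metallothionein and histone genes) are uncertain.

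The full table lists 60586 genes, of which 18870 have the status OK and a test, 41638 were not tested, 75 have the status HIDATA (too many fragments at the locus) and 3 have the status FAIL. A smaller table holds the 18870 tested genes, and its rows were checked to be identical to those of the full table. The q-values equal a Benjamini-Hochberg adjustment of the p-values over the 18870 genes within rounding, and the authors' mark of significance equals a q of at most 0.05 for each of them. The smallest p listed is 5e-05, which 4647 genes share. Fold changes were computed again from the FPKM values as MOLT4 over K562. A value of exactly 0 is given as listed at 0 and gets no fold, since a listed 0 may not be a measured level. EEF1A1, which encodes a translation elongation factor, is at 0 in K562 with the status HIDATA. The 44 genes listed on both X and Y reach at most 0.00216 FPKM in either line. Because these genes are listed at both places, their values may not be measured levels. The list members CD99, CSF2RA and IL3RA are listed at 0 in both lines, so they did not count as measured, and their absence is not shown. 14 gene names that a spreadsheet had turned into dates were restored from their identifiers. Gene positions and types are those of GENCODE release 29 on GRCh38, to which 96.5% of the identifiers matched without their version. The windows and chromosome medians below instead use the authors' deposited locus and its start, and a locus can hold several genes.

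A gene was called where the deposited q was at most 0.05. 30 gene lists were fixed before the data were examined. They are globins, erythroid membrane and surface, erythroid transcription factors and cofactors, haem synthesis and iron handling, megakaryocyte and platelet, T cell receptor complex and coreceptors, immature thymocyte, T lineage transcription factors, T cell receptor signalling, Notch pathway, granulocyte and monocyte, B cell, natural killer and cytotoxic, haematopoietic stem and progenitor, MHC class I, MHC class II, interferon response, nucleic acid sensing, cancer-testis antigens, tumour suppressors and oncogenes of leukaemia, proliferation, D cyclins and CDK inhibitors, glycolysis, cholesterol synthesis, cytosolic ribosomal proteins, cytokine receptors and JAK-STAT, chemokine receptors and lymphocyte adhesion, APOBEC and related deaminases, globin-regulating and developmental genes, and markers of other cell types. The list of D cyclins and CDK inhibitors also holds the kinase genes CDK4 and CDK6, and the APOBEC list also holds SAMHD1, which is not a deaminase gene. A member counted as measured at a mean of at least 1 FPKM over the lines. For each list with at least 3 measured members, the median of log2((MOLT4 + 1)/(K562 + 1)) was placed among 10000 random lists of the same size, drawn with replacement from 20 bins of mean expression over 14112 genes. The percentile describes these libraries and is not a p-value. The pseudocount of 1 FPKM understates the change of low genes. Members listed at 0 in a line entered the medians with that 0 as their value, although a listed 0 may not be a measured level. A list was said to stand apart outside the central 95% of the random lists. On shuffled values of the comparison of MOLT4 with K562 (14112 genes), 5% of 200 lists of 10 genes and 2.5% of 200 lists of 20 genes stood apart. With a planted log2 shift of 1, 76.5% and 94% did.

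Genes at 10 FPKM or more in a single line and under 0.1 FPKM in the other were counted without a test. Windows of 10 Mb with at least 10 measured genes were compared with random lists in the same way. Named genes followed a rule fixed before the data were examined: the 10 largest folds per direction among called genes with at least 1 FPKM in the lower and 10 FPKM in the higher line, the 10 highest genes per direction among those in a single line, the 5 most abundant genes of each line, and members of the lists. A selection of these is named, and some members of the lists are not reported here. Other thresholds, filters, pseudocounts, a centring on the median and other window sizes were tried. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.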

Results

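K562, an established line from a patient with chronic myeloid leukaemia in blast crisis that carries the BCR-ABL1 fusion, was compared with MOLT4, an established line from a patient with T cell acute lymphoblastic leukaemia. The labels describe the former as erythrocyte and the latter as T lymphoblast. The question was which genes differ in expression between the lines. The authors' table gives 1 FPKM per gene and line, and whether it combines replicates is not given in the sources used here, so no spread between replicates can be shown, and each test quoted is the authors' own. The depth is unknown. Summed FPKM was 627392 in MOLT4 and 676421 in K562, and 12877 and 13373 genes reached 1 FPKM, respectively. Both K562 figures count as 0 the 75 genes with the status HIDATA, of which 19 were above 0 in MOLT4. The median log2 ratio of MOLT4 to K562 was -0.03 over the 10960 genes at 1 FPKM or more in both lines.

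The lines differed in the genes of their lineages: K562 had the higher levels of globin, red cell membrane and haem synthesis genes, and MOLT4 the higher levels of T cell receptor, thymocyte and lymphoid transcription factor genes. In the authors' deposited table, 7958 of 18870 tested genes were called at a q of at most 0.05 (Cuffdiff with Benjamini-Hochberg adjustment), 3551 higher in MOLT4 and 4407 higher in K562. Of these, 6264 differed at least 2-fold and 4000 at least 4-fold. Among called genes with at least 1 FPKM in the lower line, the authors' deposited table gave the largest fold toward MOLT4 for TRBV20-1, a T cell receptor beta variable segment (ENSG00000211747.3, chromosome 7, 142626649 to 142627399, GRCh38), at 4376 against 3.90 FPKM (q = 0.000203). ADA, the adenosine deaminase of purine breakdown (ENSG00000196839.13, chromosome 20, 44619522 to 44652233), was at 733 against 2.62 FPKM, and TCF7, a T cell transcription factor (ENSG00000081059.20, chromosome 5, 134114711 to 134151865), at 648 against 4.85 FPKM. LAT, BEX1 and IFI16 were at 163, 182 and 125 FPKM in MOLT4 against 1.25, 1.36 and 1.95 FPKM in K562. Toward K562, again among called genes with at least 1 FPKM in the lower line, the largest fold in the authors' deposited table was that of NMU. It encodes the peptide neuromedin U (ENSG00000109255.11, chromosome 4, 55595229 to 55636698) and was at 425 FPKM against 1.07 FPKM in MOLT4 (q = 0.000203). The linker histone gene HIST1H1C was at 745 FPKM in K562 and 5.83 FPKM in MOLT4, the biliverdin reductase gene BLVRB at 287 and 2.53 FPKM, the glycophorin gene GYPC at 217 and 1.64 FPKM, and the plakoglobin gene JUP at 88.6 and 1.22 FPKM.

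Red cell genes were higher in K562. All 5 measured globins were listed higher in K562, with HBZ, an embryonic alpha-like globin (ENSG00000130656.6, chromosome 16, 152687 to 154503), at 126 FPKM and listed at 0 in MOLT4, and HBA1 at 201 against 0.0761 FPKM. Of the 5, 2 were called by the authors' deposited table, and 2 adjusted over the list alone. HBA1 was not called (q = 0.146). HBG1, HBG2 and HBE1 lie in a locus with the status HIDATA and have no usable K562 value. Of 18 erythroid membrane and surface genes, 15 were called higher in K562 by the authors' deposited table (17 adjusted over the list alone) and none higher in MOLT4. RHAG was at 279 FPKM and listed at 0 in MOLT4, ANK1 at 58.5 against 0.0330 FPKM, and TFRC, the transferrin receptor, at 181 against 130 FPKM. The median log2 ratio was -6.40 for the globins and -4.12 for the membrane genes, each at percentile 0 of matched random lists.

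Of 14 erythroid transcription factors and cofactors, 11 were called higher in K562 and 2 higher in MOLT4 by the authors' deposited table, and 13 were called adjusted over the list alone. GATA1, the leading erythroid regulator (ENSG00000102145.14, chromosome X, 48786554 to 48794311), was at 151 FPKM in K562 and listed at 0 in MOLT4. KLF1 was at 66.9 against 0.139 FPKM and GFI1B at 54.5 against 0.0521 FPKM. The exceptions were BCL11A, a repressor of fetal globin genes, at 45.4 FPKM in MOLT4 and 0.00754 FPKM in K562, and MYB, at 374 and 118 FPKM. Of 17 measured haem synthesis and iron handling genes, 12 were called higher in K562 and 1, ALAD, higher in MOLT4 by the authors' deposited table (14 called adjusted over the list alone). ALAS2, the erythroid enzyme of the first step of haem synthesis, was at 58.9 FPKM in K562 and listed at 0 in MOLT4. UROD was at 323 against 27.4 FPKM, and the ferritin genes FTH1 and FTL were at 3702 and 3222 FPKM against 809 and 783 FPKM. The list medians were -2.09 and -2.04, both at percentile 0.

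T cell genes were higher in MOLT4. Of 13 measured T cell receptor and coreceptor genes, 9 were called higher in MOLT4 and none higher in K562 by the authors' deposited table. Adjusted over the list alone 10 were called, 1 of them higher in K562. CD3E was at 446 FPKM in MOLT4 and 0.165 FPKM in K562, CD3G at 183 and 0.363 FPKM, and TRBC2, a beta chain constant region, at 3303 and 21.1 FPKM. CD3D was at 574 FPKM in MOLT4 and still at 29.7 FPKM in K562. The coreceptor genes CD4 and CD8A were low in MOLT4, at 1.03 and 7.19 FPKM, and TRAC, the alpha chain constant region, was at 13.9 FPKM. Of 13 measured immature thymocyte genes, 8 were called higher in MOLT4 and 1, AQP3, higher in K562 by the authors' deposited table (10 called adjusted over the list alone). DNTT, which adds nucleotides at receptor gene joints (ENSG00000107447.8, chromosome 10, 96304396 to 96338564), was at 322 FPKM, CD1E at 292 FPKM and CD1B at 131 FPKM, and these 3 were listed at 0 in K562. The recombinase genes RAG1 and RAG2 were at 71.3 and 67.6 FPKM against 0.949 and 0.725 FPKM. The medians were 4.58 and 5.21, each at percentile 100.

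Of 15 measured T lineage transcription factors, 13 were called higher in MOLT4 and 1, HHEX, higher in K562 by the authors' deposited table (14 called adjusted over the list alone). LEF1 was at 694 against 23.7 FPKM, GATA3 at 38.3 against 0.0895 FPKM and ETS1 at 137 against 4.68 FPKM. BCL11B was at 50.9 against 0.00363 FPKM and was not called (q = 0.369 in the authors' deposited table). Of 19 measured T cell receptor signalling genes, 13 were called higher in MOLT4 and 1 higher in K562 by the authors' deposited table (15 called adjusted over the list alone). ZAP70, the receptor's tyrosine kinase, was at 134 against 0.214 FPKM and TRAT1 at 55.8 FPKM against a listed 0. The kinase gene LCK, at 250 against 0.0480 FPKM, was not called (q = 0.0833 in the authors' deposited table), and CD69 was at 22.4 and 22.7 FPKM. The medians were 4.60 and 3.03, each at percentile 100.

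**Figure D1:**
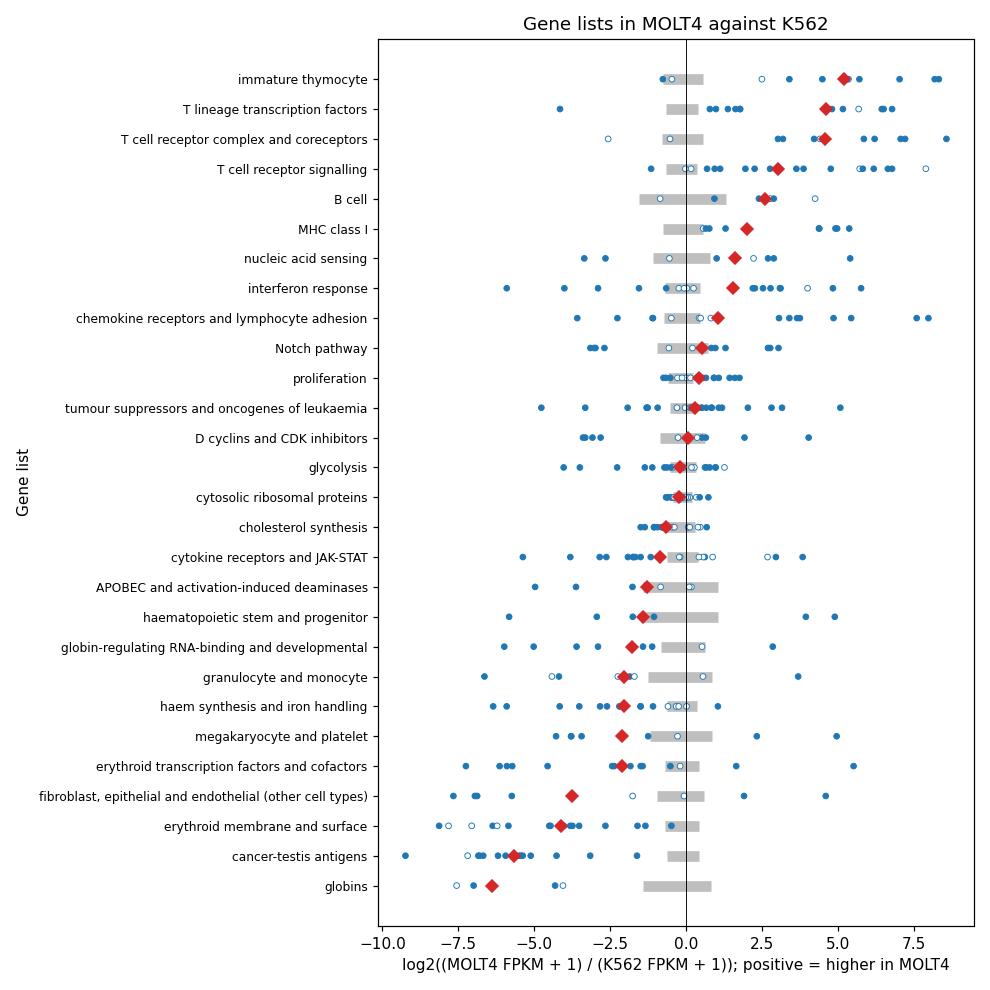
Each row is a gene list and the horizontal axis is log2((MOLT4 FPKM + 1)/(K562 FPKM + 1)). Points are measured genes (filled where the authors called them), diamonds are list medians and grey bars span the central 95% of 10000 matched random lists. The immature thymocyte median is at 5.21 and the globin median at -6.40.

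Lists of other lineages were mixed. Of 9 measured megakaryocyte and platelet genes, 5 were called higher in K562 and 2 higher in MOLT4 by the authors' deposited table (8 called adjusted over the list alone, median -2.09, percentile 0.105). ITGA2B was at 14.2 FPKM in K562 and 0.109 FPKM in MOLT4, whereas FLI1 was at 30.5 FPKM in MOLT4 and 0.00728 FPKM in K562. Of 9 granulocyte and monocyte genes, 4 were called higher in K562 and 1 higher in MOLT4 by the authors' deposited table (5 adjusted over the list alone, median -2.03, percentile 0.09). Lysozyme, LYZ, was at 105 against 0.0623 FPKM and the myeloid factor SPI1 at 17.1 FPKM against a listed 0, while the granule protease gene CTSG was at 12.0 FPKM in MOLT4 and listed at 0 in K562. Of 6 B cell genes, 3 were called higher in MOLT4 and none higher in K562 by the authors' deposited table (3 adjusted over the list alone, median 2.60, percentile 99.98). These were VPREB1, CR2 and CD72, at 6.45, 6.92 and 2.52 FPKM. Of the natural killer and cytotoxic list 2 members were measured: PRF1 was called higher in K562, at 9.53 against 0.276 FPKM, and EOMES higher in MOLT4, at 2.44 against 0.0168 FPKM, in the authors' deposited table. Of 6 stem and progenitor genes, 4 were called higher in K562, among them GATA2 at 84.1 against 0.502 FPKM, and 2 higher in MOLT4, CD34 at 14.7 against 0.0143 FPKM and ERG at 29.9 against 0.0306 FPKM, by the authors' deposited table (6 adjusted over the list alone, median -1.40, percentile 2.76, which does not stand apart). Of 8 measured markers of fibroblast, epithelial and endothelial cells, 4 were called higher in K562 and 2 higher in MOLT4 by the authors' deposited table (6 adjusted over the list alone, median -3.75, percentile 0). The keratin genes KRT8, KRT18 and KRT19 were at 218, 218 and 117 FPKM in K562 and at 0.768, 0.0841 and 0 FPKM in MOLT4, and the cadherin gene CDH2 was at 23.4 FPKM in MOLT4 and listed at 0 in K562. Of 12 Notch pathway genes, 6 were called higher in MOLT4 and 3 higher in K562 by the authors' deposited table (9 adjusted over the list alone, median 0.53, percentile 93.6, which does not stand apart). NOTCH1 was at 56.1 against 5.88 FPKM, and the Notch target HES1 was at 18.8 and 16.1 FPKM. Other members differed in either direction. DTX1 was at 5.94 FPKM in MOLT4 and 0.0111 FPKM in K562 and was called. HEY1 was at 0.0184 FPKM in MOLT4 and 7.32 FPKM in K562 and was not called.

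Antigen presentation genes of class I were higher in MOLT4. Of 11 measured members 10 were called higher in MOLT4 and none higher in K562 by the authors' deposited table (11 adjusted over the list alone, median 2.03, percentile 100). The heavy chain gene HLA-B was at 44.1 FPKM against 0.480 FPKM in K562 and HLA-C at 66.6 against 1.14 FPKM. The immunoproteasome gene PSMB9 was at 42.1 against 1.05 FPKM, and the light chain gene B2M at 1523 against 891 FPKM. None of the 13 class II members was measured, and their highest levels were 0.985 FPKM in MOLT4 and 1.05 FPKM in K562. Of 19 interferon response genes, 9 were called higher in MOLT4 and 5 higher in K562 by the authors' deposited table (15 called adjusted over the list alone, median 1.54, percentile 100). MX2 was at 67.1 against 0.246 FPKM and IFI44 at 27.7 FPKM against a listed 0, whereas IFITM1, IFITM2 and IFITM3, which restrict virus entry, were at 509, 170 and 131 FPKM in K562 against 67.6, 9.68 and 1.21 FPKM in MOLT4. Of 8 nucleic acid sensing genes, 4 were called higher in MOLT4 and 2 higher in K562 by the authors' deposited table (6 adjusted over the list alone, median 1.62, percentile 99.88). The sensor gene IFIH1 was at 8.23 against 0.240 FPKM, and the kinase gene TBK1 was at 1.89 FPKM in MOLT4 and 28.4 FPKM in K562. Of 6 APOBEC and related genes, 3 were called higher in K562 and none higher in MOLT4 by the authors' deposited table (3 adjusted over the list alone, median -1.30, percentile 3.42, which does not stand apart). These were APOBEC3B at 33.9 against 0.116 FPKM, SAMHD1 at 16.8 against 0.449 FPKM and APOBEC3C at 82.1 against 23.6 FPKM.

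Cancer-testis antigens, germline genes that tumours can express, were higher in K562. Of 16 measured, 15 were called higher in K562 and none higher in MOLT4 by the authors' deposited table (15 adjusted over the list alone, median -5.66, percentile 0). PRAME (ENSG00000185686.18, chromosome 22, 22547701 to 22559361) was at 666 FPKM in K562 and 0.104 FPKM in MOLT4, and CTCFL, MAGEB2 and MAGEA3 were at 110, 60.4 and 50.6 FPKM and listed at 0 in MOLT4. Of 9 measured globin-regulating and developmental genes, 7 were called higher in K562 and 1, DNMT3A, higher in MOLT4 by the authors' deposited table (8 adjusted over the list alone, median -1.78, percentile 0.01). LIN28B was at 36.3 against 0.153 FPKM and IGF2BP1 at 62.3 FPKM against a listed 0.

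**Figure D2:**
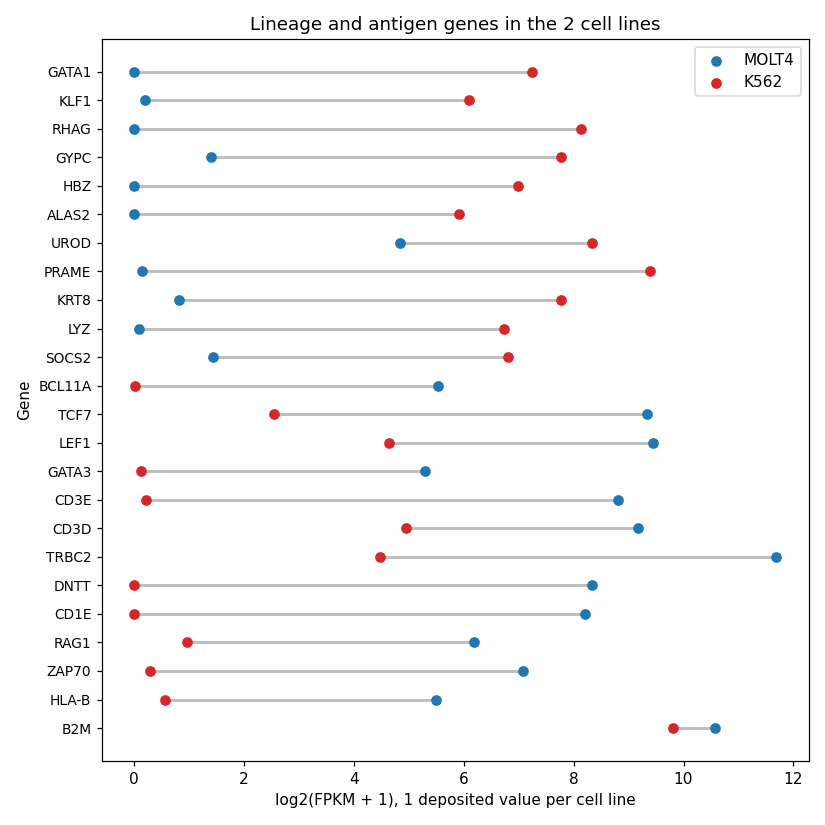
The horizontal axis is log2(FPKM + 1) of the authors' value, with 1 point per cell line and gene joined by a grey line. GATA1 is at 151 FPKM in K562 and DNTT at 322 FPKM in MOLT4, each listed at 0 in the other line, and B2M is at 1523 FPKM in MOLT4 and 891 FPKM in K562.

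Of 24 measured tumour suppressors and oncogenes of leukaemia, 10 were called higher in MOLT4 and 7 higher in K562 by the authors' deposited table (18 called adjusted over the list alone, median 0.30, percentile 97.6). BCL2, which blocks cell death, was at 11.7 FPKM in MOLT4 and 0.411 FPKM in K562. MTAP was at 33.4 FPKM in MOLT4 and 0.0116 FPKM in K562. The fusion partners BCR and ABL1 were 4.01-fold and 1.93-fold higher in K562 in the authors' deposited table, from 12.5 and 32.1 FPKM in MOLT4. These values are per gene, so transcripts of the fusion and of the unfused genes cannot be told apart. The kinase gene PIM1 was at 214 FPKM in K562 and 6.93 FPKM in MOLT4. Of 22 measured cytokine receptor and JAK-STAT genes, 12 were called higher in K562 and 3 higher in MOLT4 by the authors' deposited table (19 called adjusted over the list alone, median -0.85, percentile 0.47). The feedback inhibitor genes SOCS2 and CISH were at 111 and 40.2 FPKM in K562 against 1.70 and 1.94 FPKM in MOLT4, and IL2RG, the common gamma chain, was at 204 FPKM in MOLT4 and 13.2 FPKM in K562. Of 17 chemokine receptor and adhesion genes, 9 were called higher in MOLT4 and 4 higher in K562 by the authors' deposited table (14 called adjusted over the list alone, median 1.05, percentile 99.98). CXCR4 was at 260 against 0.0258 FPKM and ITGA4 at 249 against 0.286 FPKM, while ITGB1 was at 146 FPKM in K562 and 67.4 FPKM in MOLT4.

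Of 23 proliferation genes, 9 were called higher in MOLT4 and 3 higher in K562 by the authors' deposited table (12 called adjusted over the list alone, median 0.43, percentile 99.85). PCNA was at 713 against 209 FPKM and MKI67 at 86.3 against 27.6 FPKM, while CCNB1 was at 156 FPKM in K562 and 93.2 FPKM in MOLT4. Of 10 measured genes of the D cyclin and CDK inhibitor list, which includes the kinase genes CDK4 and CDK6, 4 were called in each direction by the authors' deposited table (8 called adjusted over the list alone, median 0.05, percentile 65.5). CDK6 was at 338 FPKM in MOLT4 against 19.5 FPKM, and CCND2 at 21.3 FPKM in K562 against 1.64 FPKM. Of 21 glycolysis genes, 8 were called higher in K562 and 5 higher in MOLT4 by the authors' deposited table (14 called adjusted over the list alone, median -0.20, percentile 34.3). Hexokinase 1, HK1, was at 239 against 20.3 FPKM, and GAPDH was at 2140.0 FPKM in MOLT4 and 1239.5 FPKM in K562. Of 21 cholesterol synthesis genes, 12 were called higher in K562 and 1, PMVK, higher in MOLT4 by the authors' deposited table (13 called adjusted over the list alone, median -0.66, percentile 1.79). CYP51A1 was at 81.2 against 28.2 FPKM. Of 33 cytosolic ribosomal protein genes, 25 were not called, 6 were called higher in K562 and 2 higher in MOLT4 by the authors' deposited table (4 called adjusted over the list alone, median -0.24, percentile 21.0).

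A total of 504 tested genes were at 10 FPKM or more in a single line and under 0.1 FPKM in the other, 319 in K562 and 185 in MOLT4. Among those listed at 0 in the lower line these counts were 127 and 44, and among those above 0 they were 192 and 141, and 990 tested genes were listed at 0 in MOLT4 against 417 in K562. Of the 504 genes, 329 were called in the authors' deposited table and 175 were not. In K562 the most abundant of them included MT1E, a metallothionein, at 785 FPKM, CPED1 at 256 FPKM and SCG3 at 174 FPKM. In MOLT4 they included FXYD2, a regulator of the sodium pump, at 598 FPKM, MAL at 271 FPKM, TRBV10-3 at 223 FPKM and SOX4 at 218 FPKM. MAL, at 0.0227 FPKM in K562, was not called (q = 0.349 in the authors' deposited table). The most abundant genes of both lines included the mitochondrial MT-ATP8, at 6822 FPKM in MOLT4 and 7580 FPKM in K562, and MT-CO2, at 4305 and 4751 FPKM. The 5 most abundant genes took 4.02% of summed FPKM in MOLT4 and 3.72% in K562. The K562 ranking and share count the 75 genes with the status HIDATA as 0, while EEF1A1, 1 of them, adds 3758 FPKM to the MOLT4 sum. The 2 shares are therefore not strictly comparable. PTMA was at 5533 FPKM in MOLT4 against 1286 FPKM, and the small cytoplasmic RNA gene BCYRN1 at 3819 FPKM in K562 against 60.4 FPKM.

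Of the 28 lists compared with random lists, 22 stood apart, 11 toward each line. With members at a mean of 10 FPKM or more, the interferon median was 0.25 (percentile 85.6) and the nucleic acid sensing median was -0.54 (percentile 16.4), so these lists no longer stood apart. With the mean in place of the median, the megakaryocyte, nucleic acid sensing, oncogene, proliferation, cholesterol and JAK-STAT lists lay inside the central 95%, and without a filter on low values the megakaryocyte, nucleic acid sensing, oncogene and other cell type lists did. Without that filter the stem and progenitor median was 0.31 (percentile 99.0) and stood apart toward MOLT4. Other medians kept their side without it but were smaller, at 1.63 for T lineage transcription factors, 0.38 for B cell genes, -0.31 for granulocyte and monocyte genes, -0.34 for JAK-STAT genes and 0.49 for chemokine receptor and adhesion genes. For the Notch list and the list of D cyclins and CDK inhibitors the mean log2 ratios were -0.04 and -0.53, opposite in sign to their medians.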

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

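5 genes at 10 FPKM or more in a line lie outside the comparison because the authors' deposited table gives them no test. EEF1A1 was at 3758 FPKM in MOLT4, TRIM22 at 31.0 FPKM and TRIM5 at 16.3 FPKM, each with the status HIDATA and listed at 0 in K562. PAICS reached 264 FPKM in MOLT4 and 241 FPKM in K562, and UHRF1 238 and 32.7 FPKM, both with the status FAIL. The tests of the status itself and of the beta-globin locus were chosen after the values were seen. That of the EEF1A1 pseudogenes was not.

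All 75 genes with the status HIDATA, in 4 loci, were listed at 0 in K562, and 19 were above 0 in MOLT4. The status stands for too many fragments at a locus, so a value listed at 0 with it is no measured absence of RNA. It is given per gene and not per line. Whether whole loci were left out of the K562 estimate cannot be told apart from other failures of the estimate, since the number of these genes above 0 in K562, 0, restates the pattern. An absence of EEF1A1 RNA from K562 is argued against by its 39 processed pseudogenes, which share its sequence and sum to 82.3 FPKM in K562 and 53.9 FPKM in MOLT4. Most of both sums came from EEF1A1P5, at 70.4 FPKM in K562 and 47.1 FPKM in MOLT4. The argument thus rests mainly on a single locus, and RNA made from that locus itself was not told apart. The related gene EEF1A2 was at 67.9 FPKM in K562 and 0.373 FPKM in MOLT4, below the 3758 FPKM of EEF1A1 in MOLT4. Whether EEF1A2 could stand in for EEF1A1 was not tested, so a need of cells for the factor is not used as an argument here. The 52 genes of the locus that holds HBG1, HBG2 and HBE1 sum to 51.2 FPKM in MOLT4, mostly TRIM22 and TRIM5 with the 3 globins listed at 0, which decides nothing on its RNA in K562, since FPKM are not fragments and the limit behind the status is not given in the sources used here. The levels of HBG1, HBG2 and HBE1 in K562 stay open.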

How the results depend on the processing

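No paired analysis was possible because the deposited table holds 1 value per line, and leaving out replicates was not run for the same reason. Depth is unknown, so what it limits cannot be stated. Of 7958 called genes (3551 higher in MOLT4, 4407 in K562), a q of at most 0.001 left 5150 (2229 and 2921), at least 4-fold left 4000 (1653 and 2347), and 1 FPKM or more in both lines, with fewer genes tested, left 4402 (2021 and 2381). The Bonferroni adjustment left 0 (0 and 0) by construction, as the smallest deposited p of Cuffdiff, 5e-05, times 18870 is 0.944, while 9124 genes had an unadjusted p under 0.05. The other settings stayed within 1.5 times. Centring on the median, a shift of -0.03, moved no call or percentile and so says nothing of stability. Settings chosen after seeing the data gave 7000 calls among genes above 0 in both lines, 6102 at 0.1 FPKM or more in both, 8133 with uncalled single-line genes added and 6490 for protein-coding genes. The 504 genes in a single line became 909 with under 1 FPKM in the other line, 843 from 5 FPKM upward and 240 with under 0.01 FPKM, and 409 for protein-coding genes, also chosen after seeing the data. The number of lists standing apart was 22, and ranged from 17 (mean in place of median) to 21 (pseudocount 0.1) under the settings that could move it. Without a filter on low values, the nucleic acid sensing median turned from 1.62 to -0.011 and that of stem and progenitor genes from -1.40 to 0.31, where it stood apart toward MOLT4 (percentile 99.0). With members at 10 FPKM or more, which left 25 of 28 lists, the former was -0.54. The causes were not tested. The megakaryocyte and other cell type lists no longer stood apart without a filter, nor the oncogene list under 4 of the settings. With the mean, 6 lists no longer did, among them proliferation, cholesterol synthesis and JAK-STAT, and the APOBEC list did. By over 1.5 times, 9 list medians lay farther from 0 with a pseudocount of 0.1 and 11 nearer to 0 without a filter, 5 lay farther and 3 nearer with members at 10 FPKM or more, and 3 means lay farther and 6 nearer than the medians. Windows past 0.05 numbered 49 of 293, 54 of 456 with 5 Mb windows and 47 of 293 with a pseudocount of 0.1.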

Other observations

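The following gene families were chosen after their values were seen, so their counts describe them and test nothing. Of 37 measured replication-dependent histone genes, 20 were called higher in K562 and 5 higher in MOLT4 by the authors' deposited table (median log2 ratio -1.52). The 20 include HIST2H2BC, which is annotated as a pseudogene. The other 12 were not called, among them HIST1H4C, at 4.92 FPKM in K562 and 5.88 FPKM in MOLT4. HIST1H2BK was at 466 FPKM in K562 and 10.4 FPKM in MOLT4, and HIST1H1B at 0.676 and 3.97 FPKM. Of 10 metallothionein genes, 8 were called higher in K562 and 1, MT1M, higher in MOLT4 by the authors' deposited table (median -2.09). MT1G was high in both lines, at 2854 FPKM in K562 and 1039 FPKM in MOLT4. Of 8 measured HOXB genes, 5 were called higher in K562 and none in MOLT4 by the authors' deposited table (median -2.53). HOXB9, at 120 against 0.00480 FPKM, was not among them.

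On chromosome 9, MLLT3, FOCAD, KLHL9 and MTAP (20341665 to 21937651, GRCh38), chosen after their values were seen, were at 8.58, 8.41, 12.6 and 33.4 FPKM in MOLT4 and at 0.101, 0.521, 0 and 0.0116 FPKM in K562. On one side ACER2, which starts at 19409059, was at 1.97 FPKM in K562 and 2.18 FPKM in MOLT4 and was not called. On the other side CAAP1, which starts at 26840685, was at 11.7 FPKM in K562 and 23.9 FPKM in MOLT4. CAAP1 was called higher in MOLT4 by the authors' deposited table. Between MTAP and CAAP1, the genes CDKN2A and CDKN2B (21967753 to 22009363) were near 0 in both lines. They were at 0.0332 and 0.0278 FPKM in MOLT4, were listed at 0 in K562 and were not tested. Of 293 windows of 10 Mb, 49 passed 0.05 after Benjamini-Hochberg adjustment of their percentiles, used as a ranking, with 29 higher in MOLT4 and 20 higher in K562. The median log2 ratio was 0.62 over the 224 genes of chromosome 13 and 0.47 over the 363 genes of chromosome 20, against -0.39 over the 1384 genes of chromosome 1.

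The test of trace levels at 30 FPKM, and those of scaling and of a few genes on chromosome 22, were chosen after the result was seen. For the BCR and ABL1 flanks the chromosome 22 window had been seen and the chromosome 9 side had not.

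Genes at a trace level in a line were called less often. Among genes at 30 FPKM or more in the higher line, 35.3% of 51 were called where the lower line was above 0 and under 0.03 FPKM, against 98.8% of 161 at 0.3 to 3 FPKM, a gap of 63.5 percentage points although the former had the larger folds, with a median log2 fold of 12.3. At 0.03 to 0.3 FPKM 77.9% of 122 were called, and of the genes listed at 0 in the lower line 89.5% of 76, so the share was lowest just above 0. At 100 FPKM or more the shares were 25% of 8 and 100% of 33, a gap of 75 percentage points (Wilson 95% intervals 7.15% to 59.1% and 89.6% to 100%), which argues against too little expression in the higher line. How the authors' test treats trace values and a wider spread between replicates at these levels both stay open, since the gap restates the pattern and values per replicate were not used here.

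The 70 measured genes in the 5 Mb centromeric to BCR (chromosome 22, 23179704 to 23318037) were higher in K562, with a median log2 ratio of -1.38, and the 34 in the 5 Mb telomeric to it had a median of 0.39, toward MOLT4, a difference of -1.77 (bootstrap 95% interval over genes -2.25 to -1.39). A single scaling factor between the lines would shift both sides alike, which that difference argues against, and a few strongly changed genes are argued against by the 87.1% of the 70 genes that were higher in K562 (Wilson 95% interval 77.3% to 93.1%). A copy gain around the BCR-ABL1 fusion that reached 2 Mb past the start of ABL1 was predicted to lower the ratio there too, but the 14 genes on that side differed from the 29 on the other by 0.20 (-0.08 to 0.68), which argues against a gain of that length. Within that side, by the authors' deposited table and chosen after their values were seen, NUP214 was at 131 FPKM in K562 and 28.8 FPKM in MOLT4 and FAM78A at 45.0 and 6.38 FPKM, while AIF1L, nearer to ABL1, was at 2.12 and 8.08 FPKM. A shorter gain on chromosome 9, or a gain of chromosome 22 alone, stays open.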
